A study of Mus musculus with 6 samples.

How the data were processed

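RNA was extracted with Trizol and a column kit, and libraries were made and sequenced by a commercial provider, per the labels' protocols. Per the submitters' processing notes, STAR, DESeq2 and the mouse build GRCm39 were used, with no version or role given. The counting tool, annotation, strand setting and filters are not given in the sources used here. The deposited table holds 1 signal value per gene and library: the authors' read counts divided by 1 factor per library, as the values themselves show. In each library the values were whole multiples of 1 step, so whole reads were recovered by dividing by that step; 100% of values came out whole within 0.01 of a read. Division by 1 factor per library is the form of DESeq2 size-factor normalization. The table had 19245 rows, and 1 row, whose gene name was broken at a bracket so that its values sat 1 column to the right, was left out. All 6 columns matched a sample by title. The labels number no replicates: the numbers 1 to 3 used here follow the order in which the samples are listed, only name a library, and pair nothing across the groups. Gene names are those of the table, and 463 rows carry Ensembl gene identifiers. Of the names, 18066 matched a symbol in a GRCm38 gene list, which was used only for names, synonyms and the order of neighbouring genes; because its build differs from the authors', no coordinates are printed.

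The recovered depth was 17507732 to 25154877 reads per library, so counting error was small beside the spread between libraries except for genes with few reads. Intervals from read counts cover counting error only. Genes with a mean normalised value of at least 10 over the 6 libraries (13962) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend and robust empirical Bayes, 1 contrast (Pten-Prkci-DKO-labelled minus Pten-KO) and 3 libraries per group. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at a false discovery rate of 0.05. A fold change on this scale understates the change of genes with low values. Means and SDs are of the normalised values. Of 32 gene lists fixed before the data were examined, the 30 with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists, and again with the correlation estimated from the data and with fry. Camera compares a list with all other genes, whereas fry asks whether a list's genes move, on balance, one way. With an estimated correlation, camera rests on only the 4 residual degrees of freedom, so it has little power here. Counts "adjusted over the list alone" used the Benjamini-Hochberg method within a list.

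The genes named were set by a rule fixed before the data were examined: Prkci, Pten and Ezh2; the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 100, non-overlapping groups and a symbol that is not a predicted-gene name; in each list the 2 called members with the smallest p, in the direction of the list's call where there was one; and the core PRC2 subunits. This gave 74 genes. List members that went against a list's direction are named in addition.

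The alternatives tried were pseudocounts of 0.5 and 5, no filter on low values, a minimum mean of 50, quantile normalization, equal library totals, limma without trend or robust prior, limma with array weights, and leaving out each library in turn. Further alternatives were the edgeR 4.0.16 quasi-likelihood test and DESeq2 1.42.0 on the recovered reads. Of these, edgeR called 3690 genes and DESeq2 3753. For lists, camera took the DESeq2 test statistics, but with edgeR it took z-scores from the count model, not the quasi-likelihood statistics. The steps were tested on simulated data. Reads drawn for 13962 genes of this comparison, with 200 changed, gave back 56.7% of the genes changed 1.5-fold, 78.5% of those changed 2-fold and 95.2% of those changed 4-fold with limma. Over 10 further draws the share of false calls averaged 8.6% and reached 13.7%, above the nominal 5%. Lists of called genes may therefore hold somewhat more false calls than the threshold states. The draws changed fewer genes than the 3679 called here and drew each gene independently, so their rates need not carry over. Read recovery on 19244 simulated genes returned 100% of the counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.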

Results

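RNA sequencing was carried out on 6 libraries from mouse prostate organoids, small gland-like structures grown from prostate epithelial cells. The labels put 3 libraries in a Pten-KO group and 3 in a Pten-Prkci-DKO group, with floxed genes cut by an adenovirus carrying Cre recombinase. Pten encodes the lipid phosphatase that restrains AKT signalling, and Prkci encodes an atypical protein kinase C of the apical polarity complex. The culture medium held dihydrotestosterone at 1 nM, epidermal growth factor at 50 ng/ml and A-8301, an inhibitor of TGF-beta type I receptors, at 200 nM. Y-27632 at 10 uM and R-spondin at 10% were also in the medium of both groups. The deposited values were read counts per gene divided by 1 factor per library, called normalised read counts below, and whole reads could be recovered from them. The recovered totals were 17955723, 19067579 and 17518439 reads for Pten-KO replicates 1 to 3 and 17507732, 22846224 and 25154877 reads for the Pten-Prkci-DKO-labelled replicates. Values are means ± SD of normalised read counts over n = 3 libraries per group, and log2 fold changes are Pten-Prkci-DKO-labelled minus Pten-KO on the log2(value + 1) scale, ± SE. The labels do not say that the libraries came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

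The targeted gene was read first, as a check of the labels. Prkci stood at 3117 ± 97.4 (SD, n = 3) in Pten-KO and at 2917 ± 364 (SD, n = 3) in the libraries labelled Pten-Prkci-DKO, a log2 fold change of -0.10 ± 0.09 that did not pass the test (limma adjusted p = 0.438). The 95% interval ran from -0.31 to 0.10, or 81.0% to 107.2% of the Pten-KO level. By library, Prkci read 3228, 3045 and 3078 in Pten-KO and 2768, 2652 and 3332 in the DKO-labelled replicates 1 to 3. Without DKO-labelled replicate 3 the log2 fold change was -0.20 and passed (limma adjusted p = 0.00754). Counts per gene include reads from any exons left in place, and the labels do not say which part of Prkci was flanked, so these counts do not check the deletion itself. Every direction below is therefore that of the libraries labelled Pten-Prkci-DKO (DKO-labelled). Pten, targeted in both groups per the labels, stood at 1728 ± 121 and 1530 ± 55.3, with a log2 fold change of -0.17 ± 0.08 (limma adjusted p = 0.129; -0.20 and adjusted p = 0.0213 without DKO-labelled replicate 3).

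**Figure D1:**
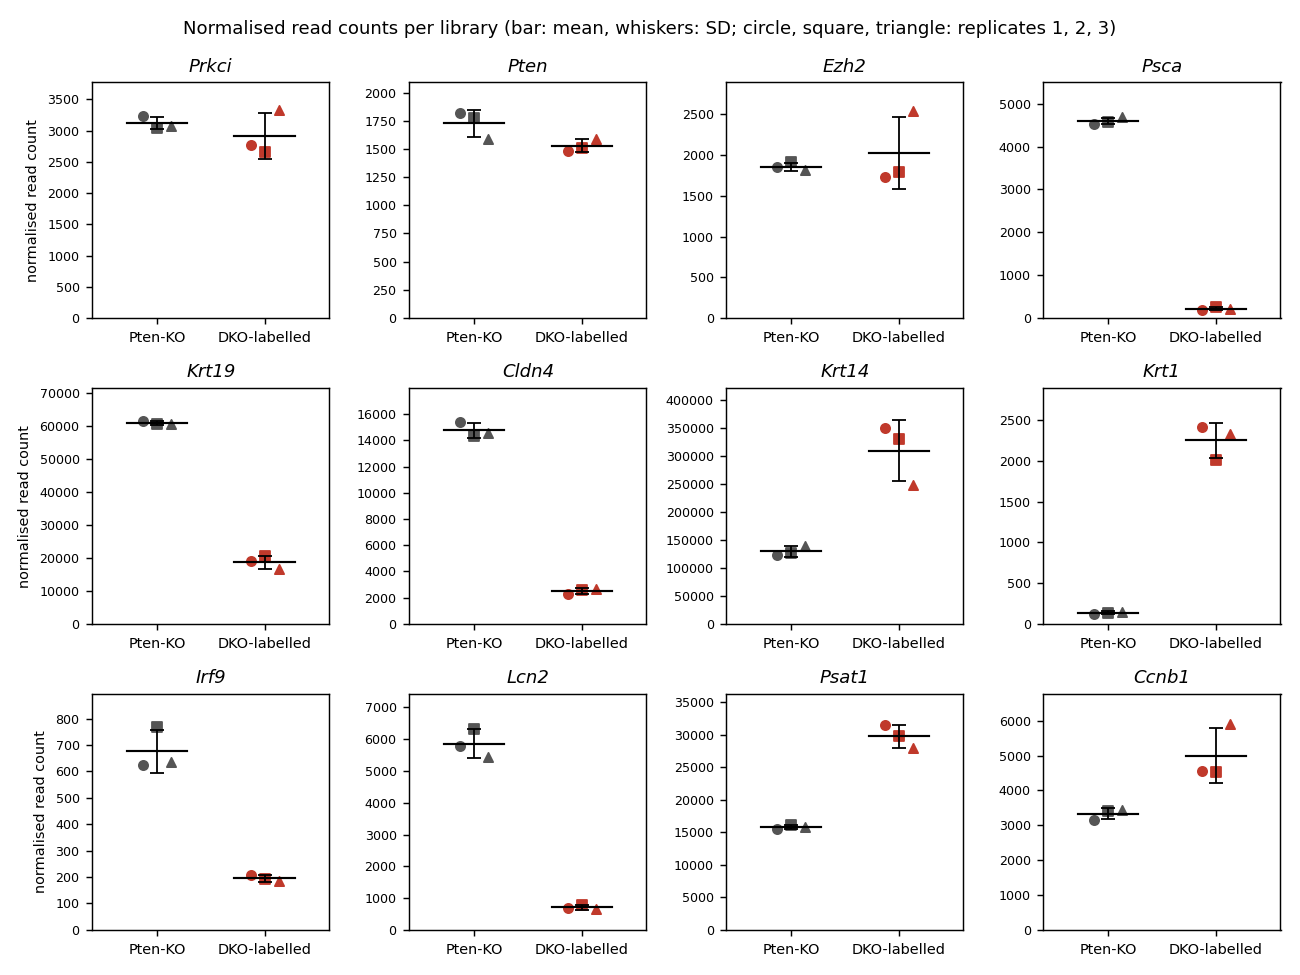
Normalised read counts per library (vertical axes, starting at 0) of 12 genes in Pten-KO and Pten-Prkci-DKO-labelled organoids; bars are means, whiskers SD, and circles, squares and triangles replicates 1, 2 and 3. Prkci, Pten and Ezh2 overlap between the groups, while Psca, Krt19, Cldn4, Irf9 and Lcn2 are lower and Krt14, Krt1, Psat1 and Ccnb1 higher in every DKO-labelled library than in any Pten-KO library.

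The comparison between the groups asks which transcripts differ when Prkci is targeted on top of Pten; the series as a whole concerns translation, EZH2 and resistance to enzalutamide, a blocker of the androgen receptor. Its design text describes a human cell line instead of mouse organoids, so only the sample labels were followed. Of 13962 genes tested, 3679 (26.4%) changed, 1591 of them higher (43.2%) and 2088 lower in the DKO-labelled libraries. Under quantile normalization 52% of the called genes were higher, and at equal library totals 34.1%, so which side held the majority depended on the scaling. Large changes leaned downwards: 988 genes changed at least 2-fold, 787 lower and 201 higher. The test was limma on log2 values at a false discovery rate of 0.05. The groups did not overlap for 6295 genes (45.1%), where chance gives 10%. The deepest falls by the naming rule included secreted and mucosal proteins. Ltf, the iron-binding lactotransferrin, went from 2389 ± 218 to 27.6 ± 11.7 (log2 fold change -6.46 ± 0.25), and Trf, transferrin, from 308 ± 35.0 to 3.15 ± 2.08 (-6.38 ± 0.40). Pigr, the receptor that carries immunoglobulins across epithelia, had 1240 reads in Pten-KO and 3 in the DKO-labelled libraries, a ratio of 485 after scaling for library depth, with an exact 95% counting interval of 166 to 2356. Eno2, a glycolytic enzyme used as a neuronal marker, fell from 357 ± 37.3 to 4.69 ± 1.37, and Klhdc7a, Lbp, Clca1 and Noxa1 fell 32.7-fold, 32.3-fold, 26.8-fold and 21.8-fold. Without DKO-labelled replicate 3 the log2 fold changes of Lbp and Clca1 were -5.64 and -5.38, over 1.5 times the fold given. At the other end, Krt1, a keratin of suprabasal epidermis, rose from 135 ± 17.4 to 2249 ± 213 (4.05 ± 0.12). The adhesion molecule Chl1 and the thioesterase Them5 rose by 3.65 and 3.07. The other 5 of the top risers share sequence with close copies and are uncertain. These were Dynlt1b (9.39 ± 0.63, with 6 reads in all of Pten-KO), Rps7-ps3 (3.91), Capza1-ps1 (3.68), Serpinb3a (3.65) and Dsg1a (3.14). Dsg1a was 3.90 without DKO-labelled replicate 3, and Dynlt1b 8.75 without Pten-KO replicate 1 and 10.14 without Pten-KO replicate 3.

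**Figure D2:**
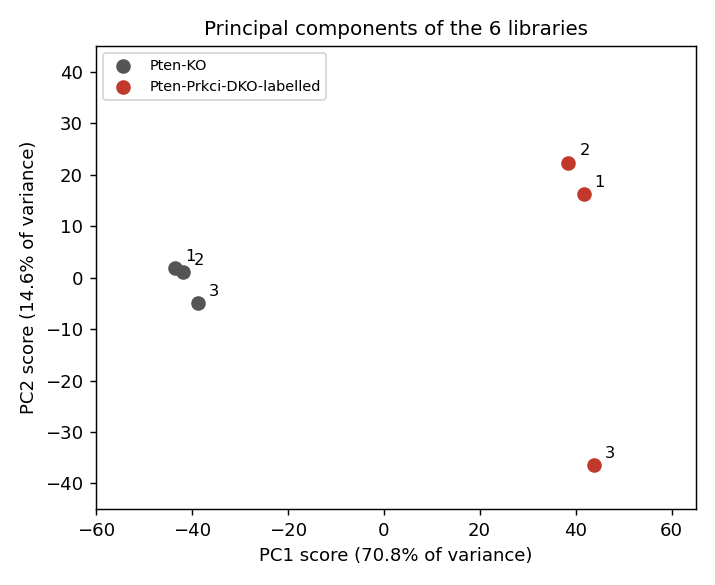
Principal component scores of the 6 libraries from log2(value + 1) of the tested genes, numbered by replicate; PC1 holds 70.8% and PC2 14.6% of the variance. PC1 separates the groups, and DKO-labelled replicate 3 lies at -36.5 on PC2, apart from its group mates at 16.2 and 22.3.

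Genes of luminal prostate cells were lower in the DKO-labelled libraries. Of 19 tested luminal markers, 15 fell, 1 rose and 3 did not pass, the counts being 15 lower and 2 higher when adjusted over the list alone, and the list median was -1.30. Psca, a surface antigen of progenitor-like luminal cells, fell from 4594 ± 78.7 to 221 ± 39.9 (log2 fold change -4.39 ± 0.12, limma adjusted p = 2.24e-08). Krt19, a simple-epithelial keratin, fell from 60790 ± 561 to 18700 ± 1996 (-1.71 ± 0.09), and Cited1 was the member that rose (1.55 ± 0.39). The list was called lower by camera (adjusted p = 2.12e-09), though not with an estimated correlation (adjusted p = 0.0533 with an estimated correlation). Androgen-regulated genes moved the same way: of 17 tested, 10 fell, none rose and 7 did not pass, and 10 were lower adjusted over the list alone. Slc45a3, known as prostein, fell from 845 ± 47.3 to 185 ± 30.9 (-2.19 ± 0.13), and the kinase gene Sgk1 from 10300 ± 437 to 3595 ± 534 (-1.53 ± 0.10). That list was called lower by camera at adjusted p = 7.74e-06 (adjusted p = 0.0581 with an estimated correlation). The 2 lists share Nkx3-1. All 4 tested markers of urothelium and seminal vesicle also fell, Upk1b from 295 ± 54.9 to 41.9 ± 8.43 and Calml3 from 136 ± 14.6 to 59.7 ± 18.1, with Upk1a and Krt20, and all 4 were lower adjusted over the list alone. Camera called that list lower (adjusted p = 0.00149; adjusted p = 0.0983 with an estimated correlation).

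Epithelial junction genes were lower as a list. Of 26 epithelial junction genes, 17 fell, 2 rose and 7 did not pass, the same counts adjusted over the list alone. The claudin Cldn4 fell from 14750 ± 559 to 2508 ± 204 (-2.56 ± 0.08, limma adjusted p = 3.36e-08) and Cldn7 from 2390 ± 53.1 to 359 ± 48.7 (-2.74 ± 0.10). The 2 that rose, Dsp (0.38) and Pkp3 (0.24), encode proteins of desmosomes, not tight junctions. The other desmosomal genes of the list were not called higher. Camera called the list lower (adjusted p = 2.12e-09; adjusted p = 0.0628 with an estimated correlation). The apical-basal polarity list held members of the apical polarity complex, to which the Prkci protein belongs, and other genes such as Scrib, Stk11 and Sqstm1. It had 6 of 18 members lower, none higher and 12 not passing, with 8 lower and 1 higher adjusted over the list alone. Pard6b, a scaffold that binds atypical protein kinase C, fell from 643 ± 28.8 to 395 ± 55.5 (-0.71 ± 0.11), and Sqstm1, an autophagy receptor, from 4574 ± 184 to 3222 ± 506 (-0.52 ± 0.11). This list was called lower (camera adjusted p = 0.0251, or 0.354 with an estimated correlation). The camera call was lost on the recovered reads with edgeR (adjusted p = 0.163) and DESeq2 (adjusted p = 0.144).

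The lists of basal and squamous markers went the other way, with exceptions among their members. Of 18 basal prostate markers, 10 rose, 2 fell and 6 did not pass, with the same counts adjusted over the list alone. Krt14, among the most abundant transcripts, rose from 129600 ± 9360 to 310100 ± 54190 (1.25 ± 0.13, limma adjusted p = 0.00011) and Krt17 from 14500 ± 1248 to 28950 ± 3426 (0.99 ± 0.10). The 2 that fell were Krt15 (-0.92 ± 0.20), a keratin of basal cells, and the transcription factor gene Sox4 (-0.69 ± 0.07). Camera called the list higher (adjusted p = 0.00305; adjusted p = 0.354 with an estimated correlation). Of 24 squamous differentiation genes, 10 rose, 3 fell and 11 did not pass, and 11 were higher and 3 lower adjusted over the list alone. Beside Krt1, the desmosomal cadherin Dsc3 rose from 2908 ± 102 to 7763 ± 1015 (1.41 ± 0.10). Those that fell were Sprr3, Sprr1a and Ivl (-2.38, -1.81 and -0.41), precursors of the cornified envelope. Camera called the list higher (adjusted p = 0.0138; adjusted p = 0.573 with an estimated correlation), and the call was lost without DKO-labelled replicate 2 (adjusted p = 0.0696). In DKO-labelled replicate 3 the median difference of the squamous members from the mean of its group mates was -0.68 log2 units, and that of the basal members -0.23.

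**Figure D3:**
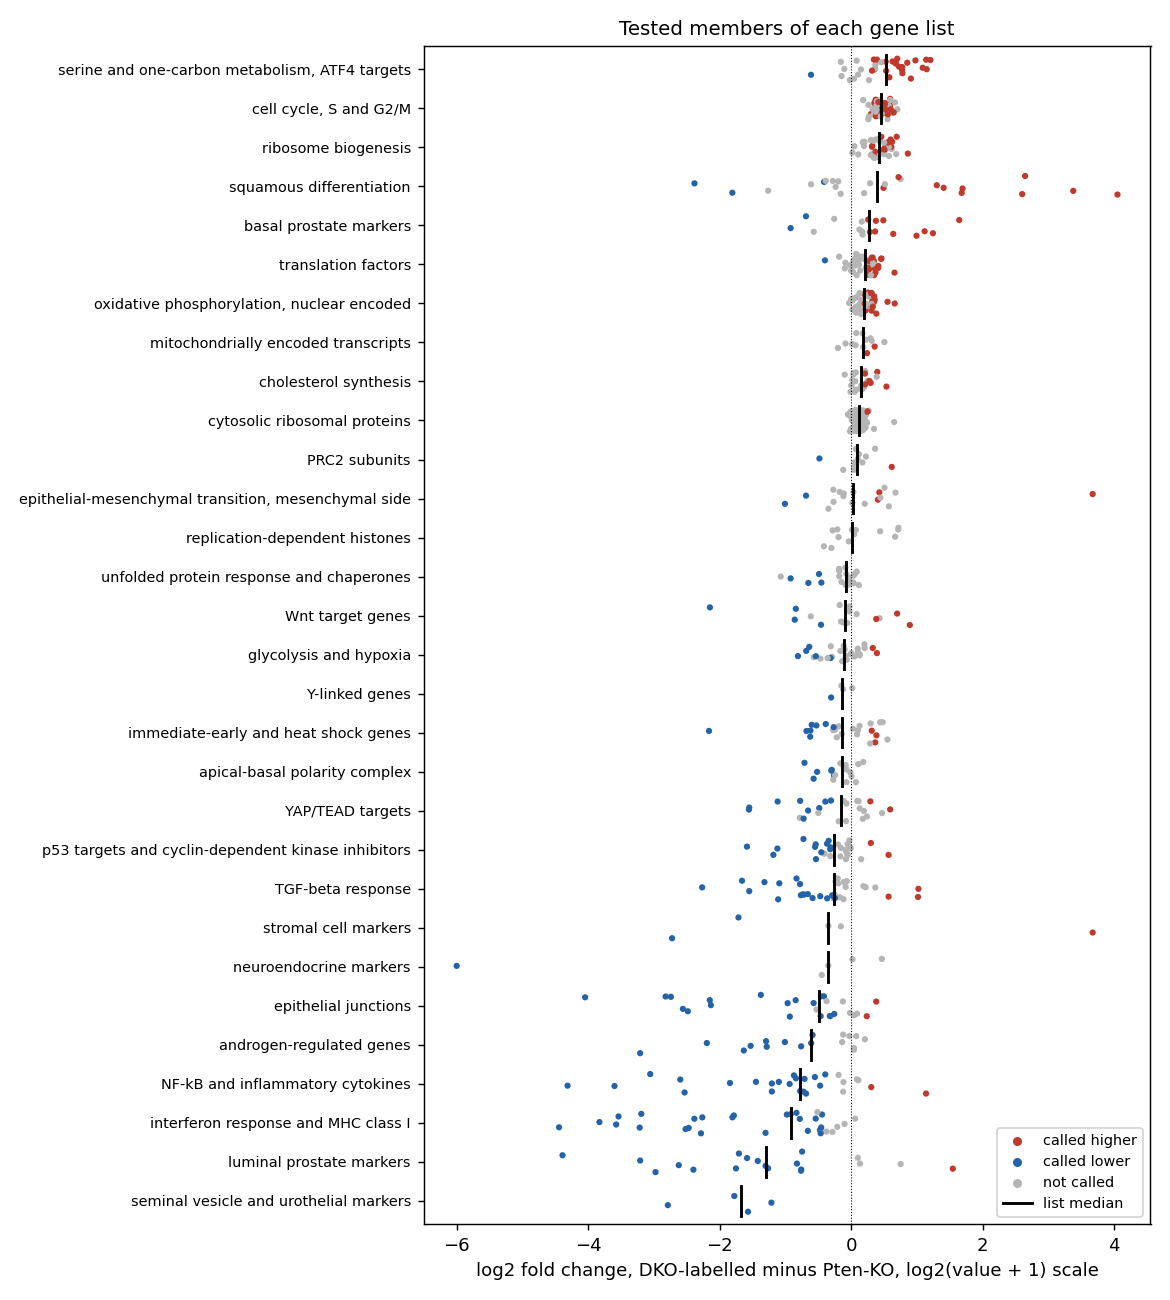
Log2 fold change (DKO-labelled minus Pten-KO, horizontal axis) of each tested member of the 30 lists tested with camera, one list per line, ordered by median; red members were called higher, blue lower, grey not called, and the black bar is the list median. Luminal, interferon and inflammatory lists lie to the left (medians -1.30, -0.92 and -0.78), while the serine and ATF4, cell cycle and ribosome biogenesis lists have the highest medians (0.53, 0.46 and 0.43).

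Interferon-stimulated and inflammatory genes were lower as lists. Of 31 interferon-response and MHC class I genes, 24 fell, none rose and 7 did not pass, and 25 were lower adjusted over the list alone. Irf9, the DNA-binding part of the interferon-activated factor ISGF3, fell from 676 ± 80.1 to 195 ± 11.9 (-1.78 ± 0.12, limma adjusted p = 4.91e-06), and Oasl2, an interferon-stimulated gene, from 264 ± 34.2 to 22.5 ± 8.22 (-3.54 ± 0.25). Of the 30 lists tested, this had the smallest camera p (adjusted p = 1.41e-12; adjusted p = 0.0533 with an estimated correlation). Of 27 NF-kB and cytokine genes, 20 fell, 2 rose and 5 did not pass, with 21 lower and 2 higher adjusted over the list alone. Lcn2, which encodes the siderophore-binding lipocalin, fell from 5854 ± 458 to 705 ± 72.1 (-3.06 ± 0.09) and the chemokine gene Cxcl2 from 1913 ± 167 to 314 ± 12.6 (-2.60 ± 0.09). Ccl2 (1.14) and Sod2 (0.31) rose. The list was called lower (camera adjusted p = 5.55e-11; adjusted p = 0.0628 with an estimated correlation). Cd68, the 1 immune marker tested, was also lower (-1.32 ± 0.27).

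Genes of serine metabolism and ATF4 targets were higher as a list. Of 35 genes of serine and one-carbon metabolism and targets of the stress factor ATF4, 22 rose, 1 fell and 12 did not pass, and 24 were higher and 1 lower adjusted over the list alone. Psat1 and Phgdh, enzymes of serine synthesis, rose from 15830 ± 314 to 29780 ± 1769 (0.91 ± 0.07, limma adjusted p = 1.99e-05) and from 5609 ± 47.7 to 9124 ± 49.4 (0.70 ± 0.06). Gdf15, a stress-induced cytokine, was the member that fell (-0.61). Camera called the list higher (adjusted p = 6.66e-11; adjusted p = 0.0581 with an estimated correlation). Nuclear genes of oxidative phosphorylation shifted by less: 17 of 47 rose, none fell and 30 did not pass, with 18 higher adjusted over the list alone. Ndufa5, of complex I, rose by 0.66 ± 0.10 and Cycs, cytochrome c, by 0.55 ± 0.08, and camera called the list higher (adjusted p = 2.67e-07; adjusted p = 0.246 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 rose, none fell and 19 did not pass, and 8 were higher adjusted over the list alone. Hsd17b7 rose by 0.54 ± 0.08 and Mvk, mevalonate kinase, by 0.40 ± 0.09 (camera adjusted p = 0.00164; adjusted p = 0.354 with an estimated correlation); Mvk did not pass limma without Pten-KO replicate 1 (adjusted p = 0.0608) or 2 (0.0663).

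The cell cycle and ribosome biogenesis lists were called higher by camera but not by fry (adjusted p = 0.0702 and 0.0728). Most of their members read higher in DKO-labelled replicate 3 than in the mean of its mates. Of 44 genes of S phase and mitosis, 23 rose, none fell and 21 did not pass, and 34 were higher adjusted over the list alone. Ccnb1, cyclin B1, rose from 3331 ± 163 to 4996 ± 784 (0.57 ± 0.10, limma adjusted p = 0.00322) and Nusap1, a spindle protein gene, from 1637 ± 77.8 to 2345 ± 263 (0.51 ± 0.09). The list median was 0.46 (camera adjusted p = 5.55e-11, or 0.400 with an estimated correlation), and 0.29 without DKO-labelled replicate 3. Members of the list lay in that replicate a median of 0.50 above the mean of its mates. Of 45 ribosome biogenesis genes, 18 rose, none fell and 27 did not pass, and 30 were higher adjusted over the list alone. Nob1, an endonuclease that matures 18S rRNA, rose from 1056 ± 66.8 to 1510 ± 50.8 (0.52 ± 0.08), and Nhp2, of the H/ACA particles, from 2432 ± 157 to 3378 ± 209 (0.47 ± 0.08). The list median was 0.43 (camera adjusted p = 1.88e-09, or 0.400 with an estimated correlation), and 0.25 without DKO-labelled replicate 3. Members of this list lay in that replicate a median of 0.57 above the mean of its mates.

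Translation, named in the series title, was represented by 2 further lists. Of 46 translation factors, 18 rose, 1 fell and 27 did not pass, with 19 higher and 1 lower adjusted over the list alone. Eif2s2, a subunit of the initiation factor eIF2, rose from 11550 ± 622 to 15900 ± 697 (0.46 ± 0.07, limma adjusted p = 0.00151) and Eif2b3, of its exchange factor, from 572 ± 36.1 to 911 ± 134 (0.66 ± 0.12), while Eif3f fell (-0.40). Camera called the list higher (adjusted p = 1.42e-05; adjusted p = 0.240 with an estimated correlation). Of 82 cytosolic ribosomal protein genes, only Rps2 (0.24 ± 0.07) and Rpsa (0.25 ± 0.08) rose, 80 did not pass, and none passed adjusted over the list alone. Both calls were lost without any single library other than DKO-labelled replicate 3 (limma adjusted p between 0.0675 and 0.166). Camera called this list higher at a median of 0.12 (adjusted p = 0.000838; adjusted p = 0.684 with an estimated correlation). The call was lost with fry (adjusted p = 0.348), under quantile normalization (adjusted p = 0.255) and without DKO-labelled replicate 2 (adjusted p = 0.204). In DKO-labelled replicate 3 the median difference of the members from the mean of its mates was -0.29. Without that library the list median was 0.24 (camera adjusted p = 2.53e-14). RNA levels do not measure translation, and no measure of translation was analysed here.

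Ezh2, the catalytic subunit of Polycomb repressive complex 2, showed no detectable difference. It stood at 1857 ± 50.0 in Pten-KO and 2022 ± 445 in the DKO-labelled libraries (0.10 ± 0.13, limma adjusted p = 0.608), with a 95% interval from -0.20 to 0.40. The sign turned without DKO-labelled replicate 3 (-0.07) and with array weights (-0.08). Eed (0.23 ± 0.09) and Suz12 (0.17 ± 0.10), the other core subunits, did not pass either, though Eed did with array weights (0.15, adjusted p = 0.0249). Of 12 subunits tested, Ezh1, the paralogue of Ezh2, fell (-0.48 ± 0.14), Phf19, an accessory subunit, rose (0.62 ± 0.20), 10 did not pass, and none passed adjusted over the list alone. Camera made no call on the list (adjusted p = 0.259), and the Ezh1 and Phf19 calls were lost without either of Pten-KO replicates 1 and 2, at adjusted p values from limma of 0.115 to 0.174. Phf19 also lost its call without Pten-KO replicate 3 (adjusted p = 0.068) or DKO-labelled replicate 1 (adjusted p = 0.0937).

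In the TGF-beta response list, 17 of 33 genes fell, 3 rose and 13 did not pass, with 20 lower and 3 higher adjusted over the list alone; the receptor inhibitor A-8301 was in the medium of both groups. The basement membrane collagen gene Col4a1 fell from 7951 ± 461 to 2515 ± 94.1 (-1.66 ± 0.07, limma adjusted p = 3.42e-07) and Ccn2, a matricellular growth factor gene, from 1028 ± 49.1 to 351 ± 19.5 (-1.55 ± 0.09). Id1, Id3 and Tgfbi rose (0.57, 1.02 and 1.02). Camera called the list lower (adjusted p = 1.28e-05; adjusted p = 0.0742 with an estimated correlation). Ccn2 also belongs to the YAP/TEAD list, where 9 of 24 fell, 2 rose and 13 did not pass, and 11 were lower and 4 higher adjusted over the list alone. F3, tissue factor, fell there by 1.55 on the log2 scale, and Birc5 (0.59) and Fjx1 (0.29) rose (camera adjusted p = 0.0257; adjusted p = 0.354 with an estimated correlation, and 0.0556 without the variance trend and robust prior). Of 28 p53 targets and cell cycle inhibitors, 12 fell, 2 rose and 14 did not pass, the same counts adjusted over the list alone. Cdkn2a, which encodes cell cycle inhibitors, fell from 1545 ± 46.7 to 721 ± 152 (-1.12 ± 0.14) and Eda2r, a p53-induced receptor gene, from 626 ± 63.4 to 275 ± 12.1 (-1.18 ± 0.11), while Perp (0.57) and Phlda3 (0.30) rose. The list was called lower (camera adjusted p = 0.00102; adjusted p = 0.246 with an estimated correlation). Of 22 unfolded protein response genes, 4 fell, none rose and 18 did not pass, the same counts adjusted over the list alone. The 4 were the sensor kinase gene Ern1 (-0.92 ± 0.09), Herpud1 (-0.49 ± 0.07), Xbp1 (-0.45) and Dnajb9 (-0.65). That call (camera adjusted p = 0.0397; adjusted p = 0.400 with an estimated correlation) was lost with edgeR (0.163), DESeq2 (0.144) and a minimum mean of 50 (0.0502), and without Pten-KO replicate 3 (0.109) or DKO-labelled replicate 1 (0.113) or 2 (0.139).

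No call was made by camera on 10 lists, PRC2 among them. In glycolysis and hypoxia 5 of 29 fell, with Hk2 (-0.54 ± 0.07) and Adm (-0.68 ± 0.10), and 2 rose, Slc2a1 (0.39) and Pfkp (0.33), at a camera adjusted p of 0.181; 5 fell and 2 rose adjusted over the list alone. The list was called lower under quantile normalization (adjusted p = 0.0122) and without DKO-labelled replicate 2 (0.0382). Of 16 Wnt targets 4 fell, with Wnt7b (-0.86 ± 0.09) and Fzd7 (-0.84 ± 0.11), and 3 rose, and of 25 immediate-early and heat shock genes 8 fell, with Jun (-0.68 ± 0.10) and Ier3 (-0.53 ± 0.10), and 3 rose (camera adjusted p = 0.345 and 0.495). Adjusted over the list alone, these counts were 4 and 3 for Wnt targets and 9 and 5 for the immediate-early list. Of 13 mitochondrially encoded transcripts mt-Nd2 (0.36 ± 0.10) and mt-Cytb (0.24 ± 0.08) rose and none fell (camera adjusted p = 0.107, and 0.0457 with no filter on low values), with 1 higher adjusted over the list alone. The mt-Nd2 call was lost without Pten-KO replicate 1 or 2 or DKO-labelled replicate 1 (limma adjusted p 0.116, 0.072 and 0.0603), and that of mt-Cytb without any single library other than DKO-labelled replicate 3 (0.0548 to 0.211). None of 13 replication-dependent histone genes changed, adjusted over the list alone or over all genes (camera adjusted p = 0.869). Among 18 mesenchymal-side genes 3 rose and 2 fell, with Acta2, smooth muscle actin, up from 8.27 ± 3.31 to 113 ± 13.1 (3.67 ± 0.29), and Mmp14 down (-0.69 ± 0.07), at a camera adjusted p of 0.529; the counts were the same adjusted over the list alone.

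Markers of other cell types were few and mostly low. Of 5 tested stromal markers, Acta2 rose, and Rgs5, a pericyte marker, fell from 40.5 ± 6.89 to 5.28 ± 1.01 (-2.72 ± 0.32), as did Dcn (-1.71), with the same counts adjusted over the list alone (camera adjusted p = 0.322). Of the immune markers only Cd68, a lysosomal protein gene of macrophages, reached the expression minimum, and it fell from 268 ± 31.8 to 112 ± 43.1 (-1.32 ± 0.27). Of 2 tested endothelial and glial markers, Pecam1 and Plp1, none passed, and with fewer than 3 tested members neither this nor the immune list was tested by camera. Of 5 tested neuroendocrine markers Eno2 was the 1 that passed over all genes, and 2 were lower adjusted over the list alone (camera adjusted p = 0.168). Camera called that list lower on the recovered reads with edgeR (adjusted p = 0.00635) and DESeq2 (adjusted p = 0.0401). Of 4 Y-linked genes Uty was lower (-0.30 ± 0.10) and 3 did not pass (camera adjusted p = 0.323), with 1 lower adjusted over the list alone. The Uty call was lost without any one Pten-KO replicate or DKO-labelled replicate 1 (limma adjusted p between 0.0635 and 0.175).

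None of the 20 list calls (9 higher, 11 lower) held with an estimated correlation, where camera has only 4 residual degrees of freedom. The estimate was below the preset 0.01 for the luminal (-0.012), androgen-regulated (0) and urothelial and seminal vesicle (-0.203) lists. Correlation among members therefore does not account for the loss of those calls. The estimate was far higher for the cell cycle (0.863) and cytosolic ribosomal protein (0.806) lists. DKO-labelled replicate 3 stood apart from its group mates (Pearson r across genes 0.984 and 0.982, against 0.992 to 0.993 for the other pairs within a group), and without it 5588 genes changed, 2669 higher and 2919 lower. List members named as exceptions to the direction of their list, and Upk1a, Krt20, Xbp1, Dnajb9, Slc2a1, Pfkp, Dcn, Pecam1 and Plp1, were chosen after their values were seen.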

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

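All alternatives here were chosen before the data were examined. Every setting moved the counts without turning any shared call: 0 genes called in both the reported fit and an alternative had opposite signs in any of the 16 alternative fits across genes. The count of genes changed (3679) was 7345 with array weights, split into 3667 higher and 3678 lower, and ran from 1897 to 5588 when single libraries were left out. The lowest came without Pten-KO replicate 1 and the highest without DKO-labelled replicate 3; without Pten-KO replicate 2 it was 2163. The share of called genes that were higher, 43.2% as reported, was 52% under quantile normalization and 34.1% at equal library totals. Leaving out a library ranged from 598 to 2669 genes higher and from 1299 to 2919 lower, from 783 to 1111 genes changed at least 2-fold, and from 18 to 20 lists called. Beside the libraries named, genes higher also fell by more than 1.5 times without Pten-KO replicate 3 (925) or DKO-labelled replicate 1 (960). Genes higher numbered 944 without the variance trend and robust prior, and 633 genes changed at least 2-fold at a minimum mean of 50, where fewer genes were tested. The Prkci log2 fold change ran from -0.202 to -0.037 over the left-out libraries and passed with array weights (-0.16, limma adjusted p = 0.00802) as it did without DKO-labelled replicate 3. That of Ezh2 reversed with array weights (-0.083) and without DKO-labelled replicate 3 (-0.072), and reached 0.20 without DKO-labelled replicate 1. With an estimated correlation 0 lists were called, 0 higher and 0 lower, against 20, 9 and 11; cytosolic ribosomal proteins stood at adjusted p = 0.684 and translation factors at 0.240. The ribosomal protein call was also lost with fry (adjusted p = 0.348) and under quantile normalization (0.255), and ranged from 2.53e-14 to 0.204 over left-out libraries, while that of translation factors stayed between 7.96e-06 and 5.01e-05. With fry 19 lists were called, ribosome biogenesis (0.0728) and the cell cycle (0.0702) dropping out and the neuroendocrine (0.00379) and stromal (0.0436) lists coming in. Directions of lists that were not called reversed in a few settings: stromal markers with no filter (adjusted p = 0.527), histones at a minimum mean of 50 (0.572) and without DKO-labelled replicate 1 (0.957) or 3 (0.935; 0.547 to 0.957 over left-out libraries), and glycolysis and hypoxia without DKO-labelled replicate 3 (0.953), a list that was called lower without DKO-labelled replicate 2 (0.0382) and under quantile normalization (0.0122). Calls were also gained by the mitochondrially encoded list with no filter (0.0457) and the neuroendocrine list with edgeR (0.00635) and DESeq2 (0.0401). The cause of these shifts was not tested. Of single named genes, 1129 comparisons with an alternative kept direction and side of the threshold, 47 lost and 5 gained the call and 2 reversed. The gained calls were those of Prkci, Pten and Eed, and the lost ones those of Rps2, Rpsa, Ezh1, Phf19, Mvk, mt-Nd2, mt-Cytb and Uty. No paired analysis was possible because the labels carry no replicate numbers; those used here are names in listing order. Depth limits only genes with few reads, such as Pigr with 3 reads and Dynlt1b with 6 reads in 1 group.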

Other observations

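Beyond the lists fixed in advance, 317 families of genes sharing a symbol stem (at least 6 tested members) were scanned with camera. The scan came after the data had been seen, so what follows is descriptive. At the preset correlation 37 families were called, and 0 with an estimated correlation. With 4 residual degrees of freedom and 317 families, the latter form had little power, so its 0 does not speak against the 37. Both directions were found, and the families named are examples, not a class of their own. Of 49 Mrpl genes, which encode the large subunit of the mitochondrial ribosome, 18 were called higher and none lower (median log2 fold change 0.26, camera adjusted p = 0.000164; adjusted p = 0.812 with an estimated correlation, as for every called family named here). Of 9 Exosc genes of the RNA exosome 8 were higher (median 0.41, camera adjusted p = 0.00303), with Exosc8 up from 969 to 1462 normalised reads. Of 8 Cct genes of the chaperonin that folds actin and tubulin 6 were higher (median 0.30, camera adjusted p = 0.0162), and Cct6a stood at 10550 against 7791. Of 7 genes in the Psmc stem, 6 were higher (camera adjusted p = 0.00626), among them 5 ATPases of the proteasome base and Psmc3ip, which is a recombination factor. All of these medians stayed above 0 without DKO-labelled replicate 3 and under each scaling.

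Examples of families called lower follow. Of 8 Cxcl chemokine genes 6 were lower (median -1.66, camera adjusted p = 0.00303), led in level by Cxcl5, which stood at 226 normalised reads against 4379 in Pten-KO. Of these 6, all but Cxcl3 are also members of the inflammatory or interferon lists. Of 15 Sprr genes, small proline-rich proteins of the cornified envelope, 10 were lower and none higher (median -1.11, camera adjusted p = 0.00345), although Krt1 and Krt10, keratins of the layers beneath that envelope, were higher (4.05 and 2.65). Members of the Sprr2 group are near-identical, so reads may be split between them. Of 16 semaphorin (Sema) genes 8 were lower and none higher (median -0.64, camera adjusted p = 0.0047). Of 19 collagen genes 10 were lower and 1 higher (median -0.59, camera adjusted p = 0.0131), with Col4a1 and Col4a2 falling by 1.66 and 1.09 on the log2 scale and Col12a1 higher (1.28). Families of intracellular proteins were called lower too, such as the Arhgef exchange factors (12 of 23 lower, none higher, median -0.32, camera adjusted p = 0.00492). Keratin (Krt) genes as a family went both ways, with 9 of 25 higher and 11 lower (median -0.80), and were not called (camera adjusted p = 0.719).

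In the weighing below, the tests of sequencing depth and of the neighbours of Prkci were fixed before their results were seen; the others were chosen after. The first pattern is the fall of luminal and junction genes beside the rise of basal and squamous markers. The sample labels give the targeting of Prkci as the difference between the groups and name no cause of the pattern. Deeper sequencing of 2 DKO-labelled libraries does not account for it. With every library thinned to 17507732 reads, 3562 genes were called against 3679. Camera then still called the luminal and junction lists (adjusted p = 1.97e-09 for each) and the basal (0.00607) and squamous (0.0135) lists. A higher share of otherwise unchanged basal cells stays open for the basal part. It would not lower a marker confined to those cells, yet abundant Krt15 fell (-0.92 ± 0.20), as did Sox4. Whether basal cells alone expressed these 2 genes was not tested, so their falls do not exclude such a higher share. A lower share of luminal cells stays open for the luminal part, where 93.8% of the called markers were lower: a loss of such cells and a lower expression within them cannot be told apart in bulk RNA. Whether the targeting of Prkci itself underlies the pattern was not tested and cannot be told in this design. The labels name no donor, litter or batch, so any such difference between the groups, or one of genetic background, would coincide with the genotype.

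The second pattern is the number of pseudogenes and gene copies among the largest rises. Among 28 genes at least 8-fold higher, 8 (28.6%) had pseudogene or predicted-gene names, against 6 of 122 (4.9%) at least 8-fold lower and 13.1% of all tested genes (two-sided Fisher exact p = 0.000788, higher against lower). This describes the pattern, partly through the low share among the falls, and decides nothing about its cause. Among the 50 tested genes nearest to Prkci, 25 on each side, 22 were called, against a median of 14 around other genes, which is the 98.5th percentile. That count is consistent with sequence carried along with the floxed allele, though neighbouring genes can also be regulated together, and it does not bear on the pseudogenes themselves. Reads moved between a parent gene and its copy stay open: the sum of Capza1-ps1 and Capza1 changed by 297 normalised reads (95% interval 4 to 590; lower limit -25 at equal library totals), and that of Rps7-ps3 and Rps7 by 2648 (-2273 to 7568; lower limit -2175). Rps7 itself stood 1182 higher, which goes against a loss to its copy but lies within that spread. The change of Capza1 itself was -873, beside a gain of 1170 for Capza1-ps1, the direction that a loss to its copy would give.

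The third pattern is that Prkci, the targeted gene, was not called lower with all 6 libraries, though it was with array weights (-0.162) and without DKO-labelled replicate 3 (-0.202). A single library swapped between the groups is excluded, because the lowest correlation within a group lay 0.0202 above the highest between groups. Exchange of the group labels as a whole would leave these correlations unchanged, so they do not test it. Deletion of only part of the gene, with reads outside it still counted, stays open and cannot be told apart from incomplete deletion here: the lower 95% limit of the log2 fold change of -0.305 is for the gene as a whole, and reads per exon were not analysed here.

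The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave 3679 genes changed, where the highest of the others gave 0; for genes changed at least 2-fold the values were 988 and 0. For lists called by camera the real split gave 20 and the highest other 17; every other split still carries part of the group difference. With fry the real split called 19 lists and the others 0. Every other split has libraries of both groups on each side, so the group difference widens its spread. That alone can bring its counts of genes and of fry lists to 0, so these counts do not bear on the real split.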
